A study of Drosophila melanogaster with 12 samples.

How the data were processed

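The series measured where the RNA helicase MLE crosslinks to RNA in Drosophila melanogaster S2 cells by uvCLAP, in 12 libraries that form 6 groups of 2. The groups are wild-type MLE (wt), the MLE mutants that the labels call GET, K, HR and KHR, and cells with an eGFP expression vector (control). Per the labels' protocols, cells were irradiated with UV-C light and the tagged protein was purified on anti-FLAG beads and then through its biotin tag under denaturing washes. Adapters were ligated, the RNA was reverse transcribed with barcoded primers, the samples were mixed, and cDNA was size-selected on a gel before an iCLIP-type library was made. A barcode at the start of the read gave the pulldown condition and a semi-random barcode at the other end gave the replicate (A or B). The labels do not say which residues each mutant name stands for. Nothing in them says that replicates A and B came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

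Each library had 2 deposited event files, marked L and M, whose meaning is not stated in the sources used here. An event was a single position on a strand with a 10-base tag of random and barcode bases. The tag fitted the barcode in the library's labels in 94.94% to 96.78% of events. The whole-number counts in the deposited event files came from reads aligned with Bowtie2 2.2.0 to the dm3 build, per the submitters' processing notes, and how duplicates were collapsed and reads filtered is not given in the sources used here. That whole number was 1 in 60.3% of events and at most 23. It was read as the number of reads behind an event, which no label states, and it was used only as an alternative weight. L and M events were summed, and each event counted as 1. The deposited combined file of each group held the same number of events as its libraries in 6 of 6 groups. The deposited gap files of each group pooled both replicates, carried a constant score in every line and were used only for gap positions and lengths. The deposited peak lists gave 1 list per MLE group from PEAKachu (positions only) and 1 from JAMM, per the file headers and names. The JAMM lists held a score for each peak that the authors deposited. It is the authors' own value and was used only to rank peaks within a list, and the lists' other values were not used. Whether peaks were called on pooled replicates, with which control and at which thresholds is not given in the sources used here.

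Libraries held from 42975 to 332817 events, 2168606 in all. Shares of a pooled file or of a group's summed events are given with exact (Clopper-Pearson) or Wilson 95% intervals, and windows with 0 events in a group with a limit of 3 events over the group. These cover counting error only. The gene annotation at hand is of another build (BDGP6), on which chromosome lengths differ from dm3 and the Het sequences of dm3 have no counterpart by name. No coordinates were carried over, no gene names were attached to positions, and features were windows of 1000 nt on each strand, as set beforehand for this case. The planned gene lists other than X-linked windows, the share of events in the roX RNAs and the profile along roX2 were therefore not made. Positions are 1-based dm3 coordinates.

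Of 88080 windows with events, the 4242 with at least 10 events in at least 2 libraries were tested. They held 70.6% of events, and 814 of them lie on X. edgeR 4.0.16 (quasi-likelihood, TMM normalization, group means over all 12 libraries, 6 residual degrees of freedom) gave log2 fold changes and Benjamini-Hochberg adjusted p-values for 13 comparisons, and windows with an adjusted p under 0.05 were called. Standard errors were taken as the fold change divided by the root of the F statistic. The estimated prior degrees of freedom were infinite, so every window took the spread of the trend across windows (biological coefficient of variation 0.0674). The spread of a window's own replicates thus did not enter its edgeR p-value. Where its replicates differed by more than the trend, that p-value is too small. TMM factors ran from 0.806 (K replicate A) to 1.287 (GET replicate B). Windows were named by a rule set beforehand: at most 5 each way per comparison with the largest fold change, among called windows with a log2 CPM of at least 6 in a group and no overlap between the replicates of both groups. X-linked windows were compared with all others with camera (limma 3.58.1) at a preset correlation of 0.01 and at an estimated one, and tested by themselves with fry. Shares and profiles were tested over all 10395 ways to pair 12 libraries into 6 groups, with the between-group sum of squares of logit shares or the within-group Hellinger distances in bins of 50 nt. This exact permutation test has no direction and a smallest p of 9.6e-05. A comparison of 2 libraries with 2 cannot go below an exact two-sided p of 0.333. Peak overlap was counted with bedtools 2.31.1 at 1 shared base or more on the same strand.

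Several regions were chosen after the data were seen. The X region and the second X region are the fullest window of X, then the fullest outside the first, each grown over neighbours on its strand with at least 10% of its events. The 3R and XHet regions were found in the same way. The 2R region is the named window lowest in GET against wt, grown over tested windows, and its segment is the longest run of 50 nt bins with at least 5 wt events in which GET held at most 5% of the wt events. The 3 GET windows hold the most GET events among windows called and at least 4-fold higher in GET than in both wt and K.

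Replicates were compared over windows with at least 20 events. The chi-square per degree of freedom was 1.04 in wt (p = 0.055) and 1.04 in GET (p = 0.091), 1.26 in KHR, 1.41 in K, 1.75 in control and 1.76 in HR. Over these windows together, the wt and GET replicates thus differed by little more than the sampling noise. Single full windows could differ more. In A and B, 3R 3300001 to 3301000 (minus strand) held 8612 and 7063 wt events and 4316 and 3753 GET events, at near-equal library totals. The replicates of no group shared an event with the same position and tag (0%). The tag holds the replicate barcode, however, so this does not tell whether replicates were split from 1 sample. Each group kept 2 libraries, and counting wt and GET as 1 library each was added as an alternative.

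Simulated counts gave every library its own total and the profile pooled over all libraries, so the groups did not differ in composition as the real ones do. Recovery in the real data may therefore differ. With 200 changed windows, the edgeR step recovered 4% of windows changed 2-fold and 33% of those changed 4-fold for wt against control (3398 windows). It recovered 21% and 73% for GET against wt (3400 windows), 24% and 73% for K against wt (3410 windows), 20% and 57% for HR against wt (3421 windows), and 13% and 47% for KHR against wt (3363 windows). The pairing test gave p under 0.05 in 5.5% of 2000 runs without groups.

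Other settings chosen before the data were examined were DESeq2 size factors, library totals, raw events with equal library sizes, the DESeq2 1.42.0 Wald test, no count filter, at least 30 events, the replicate letter as a block, only the 2 groups compared, L or M files alone, and each library left out in turn. For the X share they were also the events without the 10 fullest windows or without Het sequences, and each position counted once. The last 2 were added for the X region share. Added after seeing the data were reads as weights, scaling to events on XHet, wt and GET as 1 library each, and permutations over pairings of an A with a B library only. R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.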

Results

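MLE is an RNA helicase of the dosage compensation complex, which raises transcription from the single X chromosome of male flies and contains the noncoding roX RNAs. The title of the series names roX2. RNA crosslinked to tagged MLE was mapped by uvCLAP, a crosslinking method with FLAG and biotin purification, in S2 cells, a cultured Drosophila line. Wild-type MLE (wt), the mutants GET, K, HR and KHR, and an eGFP vector (control) were each measured in 2 libraries. The control libraries held 42975 and 46905 crosslink events in replicates A and B. The KHR libraries held 80462 and 81427, HR 113725 and 131120, GET 232843 and 232519, K 275933 and 272316, and wt 332817 and 325564. How far these totals reflect the yield of a pulldown or the sequencing depth was not separated. The files give positions on dm3 and no gene names, so regions are given by position and strand, and none is assigned to a gene.

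The question at the level of the chromosome was how much of the bound RNA came from X. In the control, 9.28% ± 0.06 of events lay on X (SD, n = 2). The share was 18.38% ± 0.08 in KHR, 25.82% ± 1.65 in HR, 27.26% ± 0.27 in GET, 41.24% ± 0.20 in wt and 47.71% ± 1.57 in K. The groups differed by more than their replicates (exact permutation test over 10395 pairings of the libraries, p = 9.6e-05, the smallest p possible). Most of this came from 1 stretch of X, from 11473001 to 11475000 on the plus strand, called the X region here and chosen after the data were seen. It held 1.78% ± 0.13 of control events, 8.47% ± 0.05 in KHR, 13.41% ± 0.37 in GET, 13.97% ± 1.47 in HR, 29.26% ± 0.23 in wt and 38.36% ± 1.66 in K (exact permutation p = 0.00029). Without the 10 fullest windows of the genome, the X share ranged from 16.41% in the control to 20.15% in wt, still a difference between groups (exact permutation p = 0.00029). Without Het sequences it was 19.79% in the control, 29.18% in KHR, 32.64% in GET, 34.48% in HR, 46.18% in wt and 55.55% in K, and the X region share was then 3.79% in the control, 13.45% in KHR and 18.65% in HR, against 16.05% in GET. With each position counted once, X took 15.64% of positions in the control, 17.54% in KHR, 19.14% in HR, 19.31% in K, 19.66% in wt and 19.75% in GET. The order of the X region turned on that measure, which caps the region at its length, with 1.12% in the control, 1.09% in KHR, 0.77% in HR, 0.59% in K, 0.45% in GET and 0.42% in wt.

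The other large contribution was XHet, the heterochromatic sequence that dm3 assigns to X and lists apart from it. It took 52.35% ± 0.35 of events in the control, 35.72% ± 0.28 in KHR, 23.28% ± 2.04 in HR, 14.28% ± 0.06 in GET, 12.72% ± 0.90 in K and 9.0% ± 0.23 in wt (exact permutation p = 9.6e-05). As numbers, however, XHet events were 47059 in the control, 57263 in HR, 57823 in KHR, 59277 in wt, 66457 in GET and 69689 in K. The fullest stretch, XHet 190001 to 192000 on the plus strand, was lower relative to the library total in every MLE group than in the control (0.157-fold in wt to 0.657-fold in KHR) but 1.04-fold (GET) to 1.38-fold (K) of the control in raw events.

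**Figure D1:**
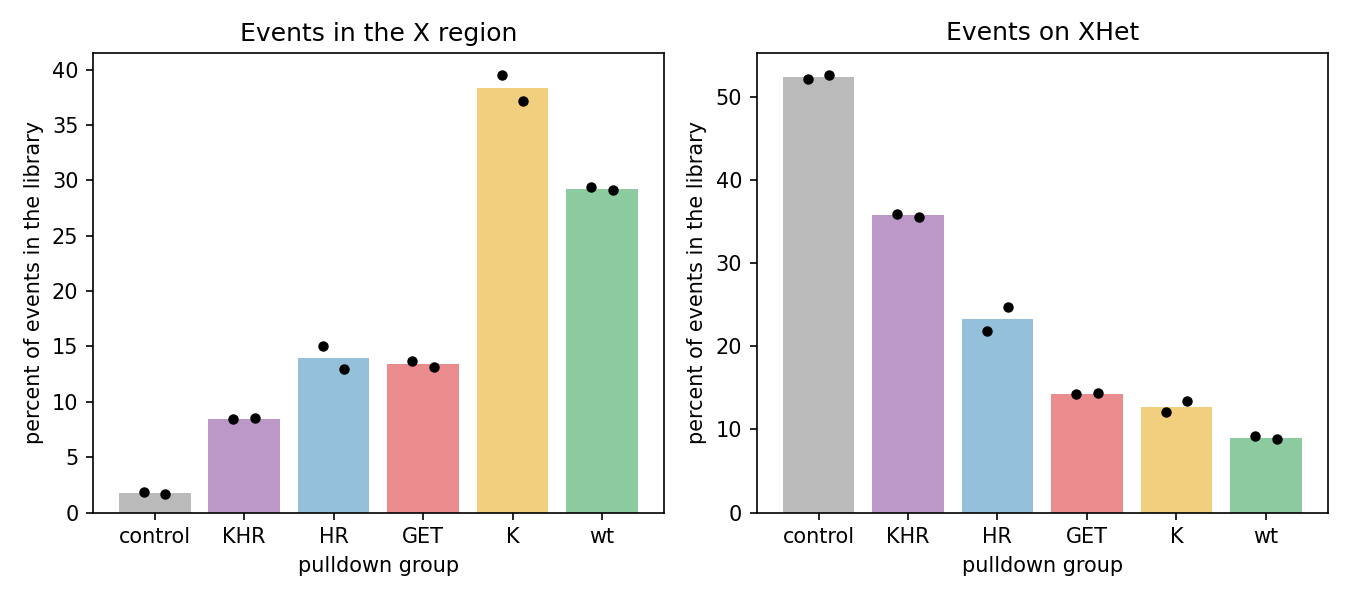
Percent of the events of each library that lay in the X region (left; X 11473001 to 11475000, plus strand) and on XHet (right), by pulldown group, with bars for the mean and points for both replicates. The X region rose from 1.78% in the control to 29.26% in wt and 38.36% in K, while XHet fell from 52.35% to 9.0% and 12.72%, although its raw number of events in wt was above that of the control.

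To find RNA held by wild-type MLE above the pulldown background, wt was compared with the control. The X region was 16.5-fold higher in CPM, events scaled to the library total (121-fold in raw events), with a log2 fold change in its first window of 3.74 (SE 0.14, edgeR adjusted p = 6.1e-144). A second stretch of X, 3753001 to 3756000 on the minus strand, was 11.7-fold higher (7075.0 ± 179.8 against 603.9 ± 100.3 CPM, n = 2), and 3R 3300001 to 3301000 on the minus strand was 6.17-fold higher (log2 fold change 2.27). Windows with the largest gains by the fixed rule had no control event at all. On 2R, 11664001 to 11665000 (minus strand) held 198 wt events, at least 9.01-fold above the control. On chromosome 4, 928001 to 929000 and 917001 to 918000 (minus strand) held 164 and 161, at least 7.46-fold and 7.33-fold above it. Windows 2R 1864001 to 1865000 (plus strand) and 3R 19193001 to 19194000 (minus strand) held 148 events each, at least 6.73-fold above it. Among losses, 2RHet 2301001 to 2302000 (minus strand) had 22 wt and 60 control events (log2 fold change −4.65, SE 0.36, edgeR adjusted p = 8e-35). In 3L 24293001 to 24294000 (minus strand) there were 12 control and 3 wt events, a 29.3-fold ratio of CPM (95% counting interval 7.91 to 162). In total 707 windows were higher and 405 lower in wt. The share of calls that were higher, 63.6%, became 84.4% with DESeq2 size factors, 77.5% with library totals, 99.9% with raw events and 99.8% when scaled to XHet events, as the median log2 fold change of all tested windows moved from 1.42 to 2.02, 1.77, 4.39 and 4.12. This median was 2.17 without control A and 3.11 without control B. The control libraries were the smallest, so windows could pass the count filter through the MLE libraries alone, which favours positive medians against the control. With no filter, 1834 windows were higher and 27 lower. Calls numbered 558 without control A and 510 without control B, instead of 1112, and ran from 478 (at least 30 events) to 3847 (raw events) over the other settings.

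All 4 mutants were also set against the same control libraries, so part of what these comparisons share may come from the control. The X region was above the control in each: 7.55-fold in GET, 21.6-fold in K, 7.86-fold in HR and 4.77-fold in KHR in CPM, with edgeR log2 fold changes in its first window of 2.50, 4.58, 2.76 and 2.25 (SE 0.14 to 0.15). The second X stretch was 9.34-fold, 8.85-fold, 4.40-fold and 10.3-fold higher in the same order. The largest GET gains were 3L 5153001 to 5154000 (minus strand, 294 events, at least 18.9-fold) and 3R 5400001 to 5401000 (minus strand, 175 events, at least 11.3-fold), both without control events. In K, 2R 1864001 to 1865000 (plus strand, 149 events) led at 8.14-fold or more, followed by 2R 10246001 to 10247000 (minus strand, 109 events, at least 5.96-fold). Chromosome 4 supplied windows again in K, HR and KHR, while no named GET gain lay on it. The window at 900001 to 901000 (minus strand) held 57 HR and 23 KHR events, at least 6.97-fold and 4.26-fold above the control, and the one at 917001 to 918000 held 104 K, 54 HR and 22 KHR events, at least 5.68-fold, 6.61-fold and 4.07-fold above it. The 2RHet window named for wt was lower than the control in GET (−3.68), K (−3.54), HR (−2.98) and KHR (−1.64, edgeR adjusted p = 0.0001). Calls were 552 higher and 261 lower in GET, 534 and 224 in K, 426 and 120 in HR, and 68 and 10 in KHR, whose libraries were the smallest among the MLE groups. With DESeq2 size factors, library totals, raw events and XHet scaling, 78.4%, 86.0%, 99.9% and 99.7% of GET calls were higher instead of 67.9%, while in a fit of only GET and the control the majority turned, with 63 windows higher and 122 lower (34.1%). For K the share was 85.2%, 61.9%, 100% and 99.8% instead of 70.4%, for HR 85.5%, 87.4%, 99.9% and 99.7% instead of 78.0%, and for KHR 82.6%, 86.7%, 100% and 99.4% instead of 87.2%. The medians of all tested windows, which the count filter favours upwards here too, were 1.47 in GET, 1.33 in K, 1.12 in HR and 0.73 in KHR. With raw events these medians reached 4.09, 3.61, 2.54 and 1.38. They were 2.25, 2.11, 1.95 and 1.23 without control A, and 3.22, 3.04, 2.85 and 1.67 without control B. Without control A the calls numbered 417 in GET, 328 in K and 207 in HR, without control B 424, 327, 198 and, in KHR, 50, and without HR A 359 in HR.

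With TMM scaling, GET had more windows called against wt than the other mutants. Its X region held 0.458 times the wt CPM, and the log2 fold change was −1.25 in the first window (SE 0.13, edgeR adjusted p = 5.9e-21) and −1.37 in the second. 3 windows stood out as gains. They were chosen after the data were seen, for the most GET events among windows called and at least 4-fold higher in GET than in wt and K. Their folds over wt are therefore no test of a gain. On 3R, 5604001 to 5605000 (plus strand) had 12525.5 ± 416.2 CPM in GET, 546.6 ± 30.1 in wt and 413.9 ± 72.8 in the control, a log2 fold change against wt of 4.38 (SE 0.13). On XHet, 193001 to 194000 (plus strand) had 7695.3 ± 357.1 in GET, 578.0 ± 92.0 in wt and 1376.4 ± 103.7 in the control (log2 fold change against wt 3.59). On 2R, 9861001 to 9862000 (minus strand) had 3317.8 ± 142.6 in GET, 706.3 ± 4.6 in wt and 155.1 ± 21.9 in the control (2.09), with 53.6% of its GET events at 1 position and 1538.6 ± 31.9 CPM in GET against 657.8 ± 16.7 in wt without it. By the fixed rule the largest gains were 3L 1329001 to 1330000 (plus strand) and X 20053001 to 20054000 (minus strand), each with 41 GET events and no wt event, at least 19.3-fold higher. In 3L 9042001 to 9043000 (minus strand) there were 112 GET and 3 wt events, a ratio of 52.8 (95% counting interval 17.6 to 260).

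The largest loss in GET was within 2R 1862001 to 1869000 (minus strand), a region that as a whole was 1.12-fold of wt in CPM and 0.793-fold in raw events. Other windows of the region had log2 fold changes from −0.61 (at 1866001) to 1.56 (at 1862001). The bin from 1867201 to 1867400, picked after the data were seen, held 56 GET and 6 wt events. The region's window 1865001 to 1866000 fell from 725 wt events to 8 (log2 fold change −6.07, SE 0.27, edgeR adjusted p = 8.6e-112). The drop covered the 450 nt from 1865551 to 1866000, where GET had 6 events, 3 in each replicate, against 3165 in the rest of the region. That is 0.19% of the region's events (95% exact interval 0.07 to 0.41), compared with 17.35% in wt (16.19 to 18.56), 15.81% in K, 16.49% in KHR and 13.14% in HR. The segment was chosen for few GET against wt events, so these intervals are no test of the difference. On the opposite strand the same window had 55 wt events and 1 GET event, a ratio of 38.9 (95% counting interval 6.69 to 1560). Other losses included 2R 10246001 to 10247000 (minus strand, 113 wt and 6 GET events, log2 fold change −3.79) and 3R 1828001 to 1829000 (minus strand, 312 and 27 events, −3.15). Over all windows 997 were higher and 853 lower. The higher share of 53.9% became 34.5%, 61.4%, 34.7% and 26.9% with DESeq2 size factors, library totals, raw events and XHet scaling, where the median was −0.47, 0.03, −0.46 and −0.63 instead of −0.11. Calls numbered 824 without GET A, 809 without GET B and 648 at a minimum of 30 events, instead of 1850, and 37.2% of calls were higher with the DESeq2 Wald test.

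**Figure D2:**
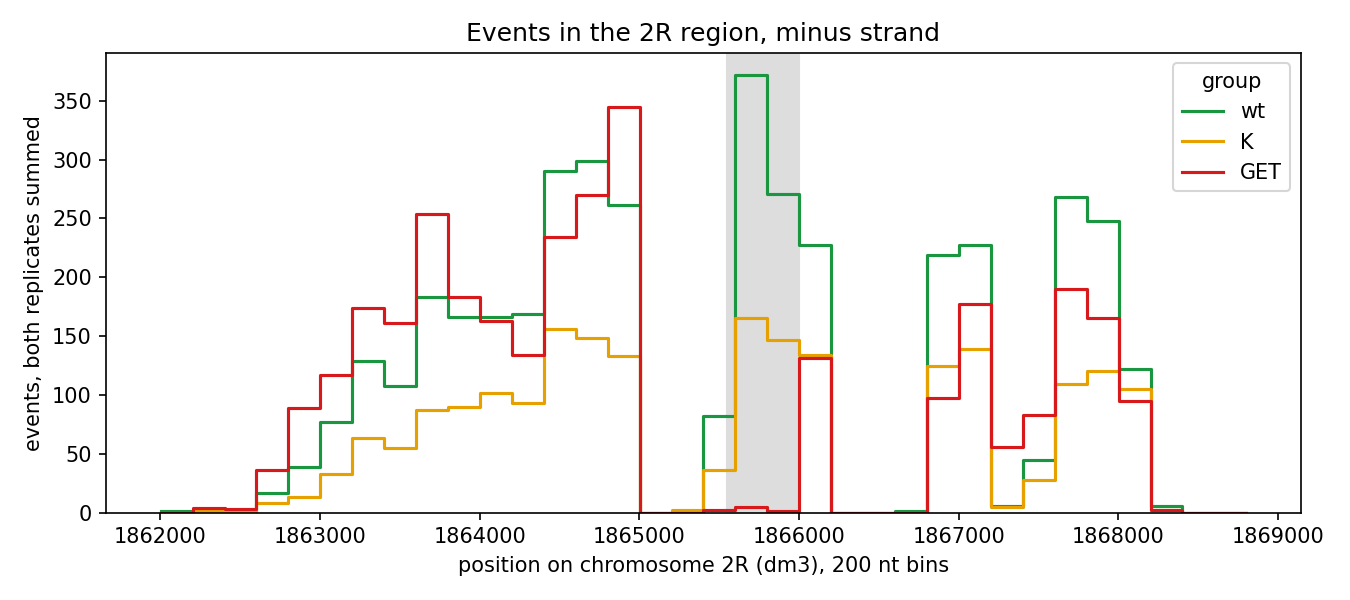
Events per 200 nt bin along 2R 1862001 to 1869000 (minus strand, dm3), summed over both replicates of wt, K and GET, with the segment from 1865551 to 1866000 shaded. GET has 6 events in the shaded segment, where wt has 694 and K 332.

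K had fewer windows called against wt than the other mutants under each of the 5 scalings. Its X region took 1.31 times the wt share of events and 1.09 times the wt events in raw numbers. The first window of the region was higher by a log2 fold change of 0.84 (SE 0.13, edgeR adjusted p = 9.3e-09), but this became 0.53 with DESeq2 size factors, 0.31 with library totals and 0.05 with raw events (adjusted p = 0.76), and turned to −0.18 when scaled to XHet events (adjusted p = 0.2). The second window was higher by 1.23 (SE 0.12, edgeR adjusted p = 8e-21) and kept its sign under every scaling, at 0.92, 0.71, 0.44 and 0.21 in the same order, with an adjusted p of 0.0015 with raw events and 0.13 with XHet scaling. The 3R window at 3300001 was not called against wt (0.14, edgeR adjusted p = 0.59), but was lower with library totals (−0.38), raw events (−0.64) and XHet scaling (−0.87). The largest gains were the neighbouring windows 3L 2811001 to 2812000 and 2810001 to 2811000 (minus strand), with 41 against 8 and 30 against 9 events (log2 fold changes 3.07, SE 0.50, and 2.46, SE 0.53), and 3R 18386001 to 18387000 (minus strand, 34 against 8 events, 2.80). Among losses, 2L 18783001 to 18784000 and 18782001 to 18783000 (minus strand) had 5 against 60 and 13 against 84 events (−2.73, SE 0.55, and −1.88, SE 0.40), and X 4833001 to 4834000 (plus strand) 8 against 65 (−2.20). Of 218 called windows 186 were higher, or 85.3%, and this majority was turned by every other scaling: 28.2% with DESeq2 size factors, 9.4% with library totals, 1.8% with raw events and 0.5% with XHet scaling, at medians of −0.29, −0.49, −0.76 and −0.99 instead of 0.02. With no filter 32.9% and with the DESeq2 Wald test 48.6% of calls were higher. The count itself was 112 without K A, 53 without K B, 89 without wt A and 67 without wt B, and ran from 44 (reads as weights) to 1993 (XHet scaling) over the other settings.

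HR held 0.478 times the wt share in the X region (log2 fold change −0.98 in the first window, SE 0.13, edgeR adjusted p = 9.8e-13, and −0.67 in the second) and 0.375 times in the second X stretch, where its 3 windows fell by 1.08 to 1.54. The 3R window at 3300001 fell by 0.82. Gains included 3L 17636001 to 17637000 (minus strand, 29 HR and 8 wt events, log2 fold change 3.35, SE 0.55) and 3R 23772001 to 23773000 (minus strand, 47 and 22 events, 2.64). Among losses, X 13588001 to 13589000 (plus strand) had 61 wt events and 1 HR event, a ratio of 22.7 (95% counting interval 3.92 to 911). Next came 2R 3249001 to 3250000 (minus strand), with 54 wt events and 1 HR event. In all 349 windows were higher and 219 lower. The higher share of 61.4% became 18.9%, 46.4%, 0.3% and 0.4% with DESeq2 size factors, library totals, raw events and XHet scaling, at medians of −0.50, −0.19, −1.60 and −1.55 instead of −0.05. Calls numbered 327, 190, 373 and 348 without HR A, HR B, wt A and wt B, instead of 568, and the other settings gave 205 (L files) to 2861 (raw events), with 25.8% of calls higher in the DESeq2 Wald test and 5.7% with no filter.

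KHR, the mutant whose name joins K and HR, was lowest in the X region, at 0.289 times the wt share (log2 fold change −1.50 in the first window, SE 0.13, edgeR adjusted p = 5.8e-29, and −1.02 in the second). The 3R window at 3300001 fell by 1.76. The second X stretch, however, held 0.883 times the wt share (6245.9 ± 218.6 against 7075.0 ± 179.8 CPM), and its middle window was higher than wt by 0.45 (edgeR adjusted p = 0.0043), which turned to −0.29 with DESeq2 size factors, −1.95 with raw events and −1.92 with XHet scaling. Windows with no KHR event were 2R 10246001 to 10247000 (minus strand, 113 wt events, at least 9.26-fold lower), X 12558001 to 12559000 (plus strand, 107 wt events, at least 8.77-fold lower) and 2L 7953001 to 7954000 (minus strand, 71 wt events, at least 5.82-fold lower). The largest gains were 3L 24293001 to 24294000 (minus strand), with 28 KHR and 3 wt events (ratio 38, 95% counting interval 11.7 to 195), and 3R 18386001 to 18387000 (minus strand), with 33 and 8 events (log2 fold change 4.37, SE 0.52). The 3L window was also named as lower in wt than in the control. It held 28 of 161889 KHR events and 12 of 89880 control events, so the gain over wt is not shown to be one over the control. In all 526 windows were higher and 519 lower. The higher share of 50.3% became 17.8%, 29.6%, 0.2% and 0.2% with DESeq2 size factors, library totals, raw events and XHet scaling, at medians of −1.20, −0.85, −2.83 and −2.79 instead of −0.48. Calls numbered 578 and 525 without KHR A and KHR B, instead of 1045, and the other settings gave 372 (L files) to 3463 (raw events), with 23.9% of calls higher in the DESeq2 Wald test and 7.1% with no filter. The near-even split also turned without wt A (49.8%), without wt B (49.6%) and with reads as weights (45.9%).

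Direct tests between mutants asked whether the effects of K and HR differed from that of KHR and from each other. The first window of the X region was lower in KHR than in K (log2 fold change −2.33) and than in HR (−0.52, SE 0.14, edgeR adjusted p = 0.0029), lower in HR than in K (−1.82) and lower in GET than in K (−2.08), and kept these signs under every scaling. In the second window the values were −2.25, −0.35, −1.90 and −2.60 in the same order. The difference of KHR from HR was not called there (SE 0.12, edgeR adjusted p = 0.072), although it was with each other scaling (−0.59 to −1.22). The second X stretch went the other way between KHR and HR, with 2.35 times the HR share in KHR (1.57 times in raw events). Its 3 windows were higher by 1.44 to 1.53. KHR had no events in 2R 10246001 to 10247000 (minus strand), where K had 109 (at least 10.7-fold lower), nor in X 8821001 to 8822000 (minus strand), where HR had 27 (at least 5.95-fold lower). HR exceeded K in 3L 11435001 to 11436000 (plus strand, 33 against 5 events, log2 fold change 3.44, SE 0.58) and fell short of it in X 3752001 to 3753000 (minus strand, 6 against 91, −3.10), which adjoins the second X stretch. GET fell below K in the 2R window at 1865001 (8 against 350 events, −5.81) and in 2R 10246001 to 10247000 (6 against 109, −4.52). Higher and lower calls were 272 and 360 for KHR against K, 104 and 96 for KHR against HR, 71 and 114 for HR against K, and 768 and 733 for GET against K. With DESeq2 size factors, library totals, raw events and XHet scaling, 15.4%, 54.5%, 0.0% and 0.1% of calls were higher for KHR against K instead of 43.0%, and 22.5%, 25.4%, 1.0% and 1.0% for KHR against HR instead of 52%. For HR against K they were 25.2%, 82.1%, 2.1% and 5.9% instead of 38.4%, and for GET against K 48.4%, 86.8%, 77.8% and 80.9% instead of 51.2%. For KHR against K, 277, 236 and 341 windows were called without KHR A, KHR B and K A instead of 632, and the majority turned to higher without KHR A (62.1%), KHR B (58.5%) or K B (50.4%), in a fit of only these groups (61.9%), at a minimum of 30 events (57.6%) and with L files only (52.9%). For KHR against HR, 91, 81, 114 and 125 were called instead of 200 without KHR A, KHR B, HR A and HR B. With reads as weights 31.3%, with no filter 20%, with the DESeq2 Wald test 27.8% and with wt and GET as 1 library each 49.3% of calls were higher in that comparison. For HR against K, 110, 81, 120 and 121 were called instead of 185 without HR A, HR B, K A and K B, and for GET against K 679, 705 and 980 instead of 1501 without GET A, GET B and K A, with 49.3% of calls higher when wt and GET counted as 1 library each.

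Within the X region, the position of events was compared along its length, of which 11473394 to 11474172 held 98.8% to 99.1% of events in every group. The profiles differed between groups by more than between replicates (exact permutation test on 50 nt bins, p = 9.6e-05). GET had the largest share from 11473701 to 11473800, at 42.68% ± 1.68 (n = 2) against 33.12% ± 0.65 in wt, 33.70% ± 0.70 in K, 36.41% ± 1.19 in HR, 32.64% ± 0.23 in KHR and 34.34% ± 0.34 in the control. From 11473801 to 11473900, wt held 31.55% ± 0.04, the control 27.88% ± 0.55, K 25.99% ± 0.74, GET 23.61% ± 0.01, HR 22.14% ± 0.03 and KHR 21.54% ± 0.67. From 11474001 to 11474100, KHR held 16.61% and wt 9.71%. These bins were picked after the profiles were seen, and single pairs of groups cannot be tested below an exact p of 0.333.

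**Figure D3:**
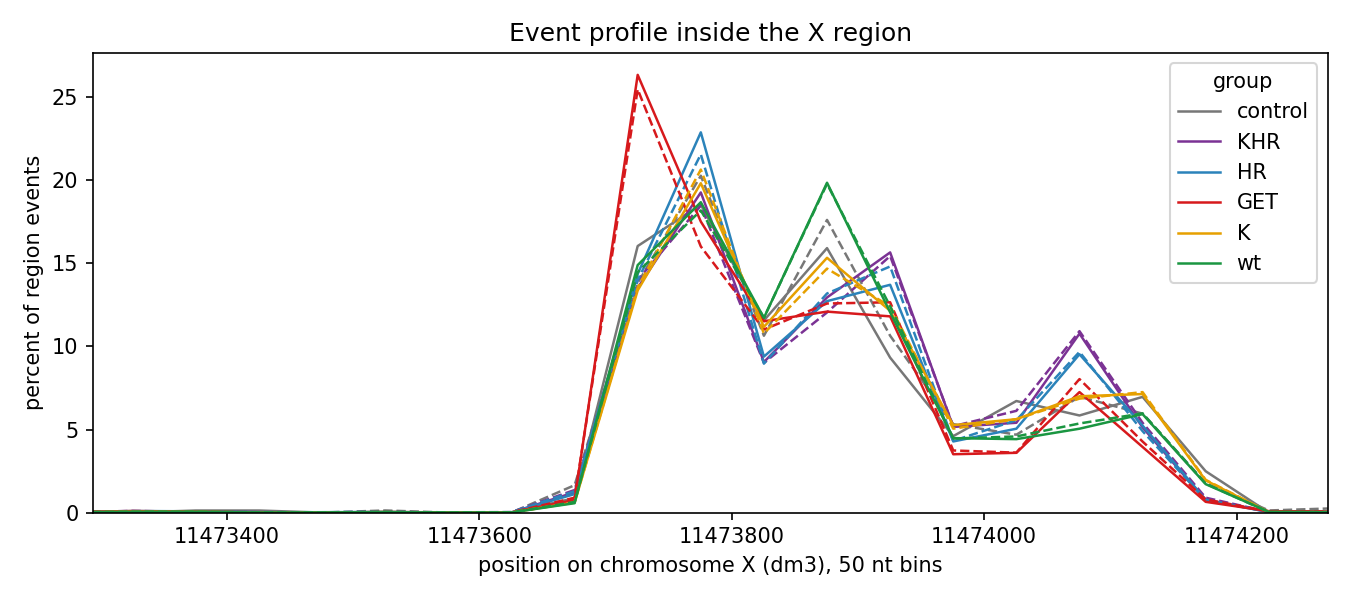
Percent of the X region's events per 50 nt bin along X (plus strand, dm3), with a solid line for replicate A and a dashed line for replicate B of each group. GET peaks in the bin from 11473701, at 26.3% and 25.5% in replicates A and B, and wt is the highest group in the bin from 11473851, at 19.9% and 19.8%.

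The X-linked windows as a class, the only planned list that could be made, were compared with the 3428 other windows. Between wt and the control the median log2 fold change was 1.71 on X and 1.36 elsewhere, with 138 of 814 X windows higher and 52 lower (131 and 50 when adjusted over the list alone). Against the control the X median was 1.82 in GET, 1.67 in K, 1.48 in HR and 0.74 in KHR, above the others in each case (1.39, 1.31, 1.10 and 0.65). Against wt it was −0.06 in GET, 0.01 in K, −0.01 in HR and −0.57 in KHR, where 67 X windows were higher and 112 lower (64 and 103 when adjusted over the list alone). None of the 13 comparisons passed camera after adjustment, with adjusted p of 0.26 for wt against control and for KHR against wt, and 0.082 for both with an estimated correlation. At an unadjusted p under 0.05, camera found 1 comparison with the preset correlation and 7 with an estimated one, and fry, which tests the X windows without the others, found 9. Camera's direction and the sign of the X median differed in 3 comparisons: X windows were placed below the others for K against wt (median 0.01) and above them for GET against wt and HR against K (both −0.06). For HR against wt camera placed them below the others, whose median of −0.06 was under the X median of −0.01. The direction of fry was opposite to that of camera for K and HR against wt and HR against K.

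The authors' deposited peak lists can be compared only by size, place and overlap, since there is 1 per group. PEAKachu gave 381 peaks in wt, 336 in GET, 128 in K, 34 in HR and 24 in KHR. On X lay 26.2% of wt peaks (95% interval 22.1 to 30.9), 22.3% in GET, 46.1% in K, 50% in HR and 100% in KHR (86.2 to 100). The X region held 21 of these peaks in wt, 17 in K, 13 in GET, 13 in HR and 12 in KHR, and the second X stretch held the other 12 of KHR. The 2R region had 55 wt, 26 GET and 11 K peaks. In the JAMM lists the X region held 1 peak in wt, 1 in K, 6 in GET, 5 in HR and 4 in KHR, the second X stretch 6, 7, 13, 10 and 6, and the 2R region 13, 13, 13, 11 and 11 in the same order. Of PEAKachu peaks, 33.0% in GET (28.2 to 38.2), 91.4% in K (85.3 to 95.1), 97.1% in HR and 100% in KHR overlapped a wt peak. JAMM gave 19263 peaks in wt, 14989 in GET, 11150 in K, 5373 in HR and 2454 in KHR, of which 19.8%, 20.5%, 22.4%, 18.3% and 16.4% lay on X. In the JAMM lists 20.6% of GET, 24.3% of K, 25.7% of HR and 20.1% of KHR peaks overlapped a wt peak.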

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

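The gaps within aligned reads, deposited as 1 pooled file per group, were used in no comparison above. The share of gaps that lay inside the X region was above the control in every MLE group: 16.3% in GET, 21.1% in HR, 12.9% in KHR, 38.8% in K and 32.8% in wt, against 4.9% in the control (95% interval 3.6 to 6.5). The files held 938 gaps in the control, 8527 in GET, 3922 in HR, 2577 in KHR, 11810 in K and 12818 in wt. Per 1000 events inside the region, the control had 28.9 gaps and the MLE groups 21.8 to 24.4. Per 1000 events outside it, the control had 10.1 gaps and the MLE groups 14.67 (HR) to 21.38 (K). For gaps of at least 40 nt the rate inside was 6.9 in the control and 3.2 (wt and K) to 5.3 (KHR) in the MLE groups. With each distinct gap counted once, the share inside the region in GET, 5.2% (4.7 to 5.8), overlapped that of the control, 4.1% (2.9 to 5.7).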

How the results depend on the processing

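Added after the data were seen were scaling to XHet events, reads as weights, wt and GET as 1 library each, pairings of A with B libraries only, and the X region, XHet and profile results. Of the comparison results, 282 values under other settings kept their side of the threshold or stayed within the spread, and 145 moved. For numbers of called windows only the total was compared, so a value that stayed may hide a turned majority. K against wt with DESeq2 size factors counted as stayed, with 216 calls instead of 218, although 28.2% instead of 85.3% were higher. Of the values for single groups and for the windows the text describes, 2924 stayed, 312 lost and 18 gained a call, 71 moved and 28 reversed. Windows named by the fixed rule reversed under no setting. Fewer windows or events enter with at least 30 events, L or M files or a library left out; for the other settings the cause was not tested. For wt against control, changes of 2-fold were recovered in 4% of simulated windows. The simulation left out the groups' differences in composition and the other control comparisons, and it did not test depth as the cause. The planned roX share, roX2 profile and other gene lists, and a stricter PEAKachu list (no score), were not run. Counting each event line once is the count already used, and windows are already the features.

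With raw events, 3847 windows were called for wt, 3872 for GET, 3562 for K, 2270 for HR and 416 for KHR against control, 1252 for K, 2861 for HR and 3463 for KHR against wt, 2574 for KHR against K, 774 for KHR against HR and 959 for HR against K. Scaled to events on XHet, there were 3658, 3599, 2931, 1818 and 172 against control (wt, GET, K, HR, KHR), 1993, 2775 and 3434 against wt (K, HR, KHR), 2093 for KHR against K, 812 for KHR against HR and 489 for HR against K. DESeq2 size factors gave 1946 for wt against control and 1799 for KHR against wt. Library totals gave 1352 for GET against control, 530 for K against wt and 335 for HR against K. The DESeq2 Wald test gave 355 for HR against control, 1107, 70 and 298 for GET, K and HR against wt, 100 for HR against K and 681 for GET against K.

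With no filter, 1861 and 1390 windows were called for wt and GET against control, 1048 and 73 for GET and K against wt, 75 for KHR against HR and 706 for GET against K. With at least 30 events in 2 libraries, there were 478, 433, 431 and 354 for wt, GET, K and HR against control, 648, 308 and 402 for GET, HR and KHR against wt, 323 for KHR against K and 596 for GET against K. With only the 2 groups compared, 714 were called for wt against control, 185 for GET against control (63 higher and 122 lower, which turned the majority) and 62 for K against wt.

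L files only gave 578, 458, 385 and 277 for wt, GET, K and HR against control, 696, 76, 205 and 372 for GET, K, HR and KHR against wt, 206 for KHR against K, 78 for KHR against HR, 83 for HR against K and 606 for GET against K. M files only gave 635, 472, 370, 219 and 46 for wt, GET, K, HR and KHR against control, 880, 80, 215 and 486 for GET, K, HR and KHR against wt, 261 for KHR against K, 78 for KHR against HR, 64 for HR against K and 680 for GET against K. Reads in column 5 as weights gave 129 for KHR against control, 919, 44 and 246 for GET, K and HR against wt, 131 for KHR against HR, 89 for HR against K and 751 for GET against K. With wt and GET counted as 1 library each, 970, 93 and 359 were called for GET, K and HR against wt and 898 for GET against K.

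Leaving out each library in turn gave 510 to 1229 windows for wt, 417 to 683 for GET, 327 to 893 for K, 198 to 436 for HR and 50 to 92 for KHR against control. Against wt the ranges were 809 to 1291 for GET, 53 to 112 for K, 190 to 373 for HR and 525 to 867 for KHR. Between mutants they were 236 to 516 for KHR against K, 81 to 125 for KHR against HR, 81 to 121 for HR against K and 679 to 1077 for GET against K. A group's lone library was assumed to vary like the others. The permutation p-values that follow are unadjusted, while the camera p are at the preset correlation and Benjamini-Hochberg adjusted over the 13 comparisons. The exact permutation p ran from 9.6e-05 to 0.00019 for the X share and the XHet share, 9.6e-05 to 0.00029 for the X region share and 9.6e-05 to 0.0011 for the profile. The camera p of X-linked windows ran from 0.21 to 0.28 (wt), 0.12 to 0.28 (GET), 0.22 to 0.37 (K), 0.22 to 0.28 (HR) and 0.74 to 0.94 (KHR) against control, 0.74 to 0.9 (GET), 0.68 to 0.88 (K), 0.72 to 0.87 (HR) and 0.21 to 0.39 (KHR) against wt, 0.29 to 0.39 for KHR against K, 0.26 to 0.39 for KHR against HR, 0.9 to 0.99 for HR against K and 0.72 to 0.89 for GET against K.

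The labels give the replicate letters as 3′ barcode classes, which the libraries of a letter share, and name no shared culture, batch or day, so the letters were not taken as pairs. Deviations of the A libraries correlated between groups at r = −0.04 to 0.28 over 15 pairs of groups (111 windows), over 0.1 in 6 pairs. By these values 12 of 12 libraries correlated best with a library of their own letter. The deviation of a B library mirrors that of its A partner, so this counts 6 values 2 times. It is at most a hint from the data and not the design. With the replicate letter as a block, 1071, 775, 729, 527 and 74 windows were called for wt, GET, K, HR and KHR against control, 1784, 212, 542 and 1015 for GET, K, HR and KHR against wt, 600 for KHR against K, 197 for KHR against HR, 186 for HR against K and 1447 for GET against K, none moved by over 1.5 times. Relative to library totals, the 3R region and the second X region were higher in A than in B in 6 of 6 groups. In a test added after the data were seen, only the 720 pairings of an A with a B library were used (replicate block). The exact permutation p was then 0.0014, the smallest possible, for the X share, XHet share and profile, and 0.0028 for the X region share.

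The first X region window, K against wt, turned to −0.18 when scaled to XHet events. The 3R window 3300001 to 3301000 (minus strand), K against wt, turned to −0.38 with library totals, −0.64 with raw events and −0.87 scaled to XHet events. For KHR against wt on X (minus strand), the window at 3753001 turned to 0.36 with at least 30 events and 0.33 with only the 2 groups. The window at 3754001 turned to −0.29 with DESeq2 size factors, −1.95 with raw events, −0.29 with the Wald test, −0.74 with no filter and −1.92 scaled to XHet events. The window at 3755001 turned to −0.5, −2.18, −0.5, −0.96 and −2.14 in the same order. XHet 190001 to 191000 and 191001 to 192000 (plus strand) were lower than the control in each MLE group but turned with raw events to 0.31 and 0.14 in wt, 0.03 and 0.07 in GET, 0.46 and 0.48 in K, 0.33 and 0.23 in HR and 0.29 and 0.21 in KHR. The first of them also turned to 0.04 in HR when scaled to XHet events and to 0.06 in KHR with no filter.

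The median log2 fold change of all windows against the control was 1.72, 1.95 and 3.65 in GET, 1.64, 1.17 and 3.09 in K, 1.29, 1.34 and 2.37 in HR and 0.62, 0.70 and 1.14 in KHR with DESeq2 size factors, library totals and XHet scaling. L files only gave 1.83 in HR and 1.16 in KHR, and no filter 0.30 in GET, 0.49 in K and 0.00 in HR and KHR. The size of the medians against the control thus depended on the count filter. With only the 2 groups KHR turned to −0.03. Between mutants, DESeq2 size factors, library totals, raw events and XHet scaling gave −0.78, −0.23, −1.93 and −1.67 for KHR against K instead of −0.37, −0.56, −0.52, −1.10 and −1.11 for KHR against HR instead of −0.28, −0.20, 0.31, −0.83 and −0.54 for HR against K instead of −0.06, and −0.19, 0.51, 0.28 and 0.35 for GET against K instead of −0.14.

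Among JAMM peaks at or above their list's median score, 14.2% of GET, 14.9% of KHR and 18.9% of K peaks lay on X. At an overlap of at least 50% of the shorter peak, 84.4% of K PEAKachu peaks and 17.7% of GET, 22% of HR, 17.7% of KHR and 20.6% of K JAMM peaks overlapped wt, and without strand 21.6% of GET, 27.5% of HR and 26.0% of K JAMM peaks. The X region share in the control was 2.82% in L and 1.1% in M files. Of gaps of at least 40 nt, 2.8% in control, 6.5% in GET, 10.5% in HR, 7.5% in KHR, 18.6% in K and 15.1% in wt lay in the X region. With each distinct gap counted once, the shares were 4.1% in control (95% interval 2.9 to 5.7), 5.2% in GET (4.7 to 5.8, which overlaps the control), 9.8% in HR, 8.2% in KHR, 11.4% in K and 8.8% in wt.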

Other observations

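Chromosome 4 took 0.81% ± 0.01 of control events (n = 2), 1.21% ± 0.04 in K, 1.39% ± 0.04 in wt, 1.41% ± 0.04 in KHR, 1.52% in GET and 1.63% ± 0.01 in HR. On 2L the share was 8.44% ± 0.14 in K, 8.93% ± 0.05 in the control, 10.54% ± 0.06 in wt and 12.42% ± 0.09 in GET. These differences were not tested, and each share also moves with the shares of XHet and the X region.

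The patterns below were found in the data. The tests of event number, opposite strand, mle identity, library depth and X region identity, of windows without their fullest position and of tags, and the expected number of gaps, were chosen after the result was seen. Rules for reading the opposite-strand, mle and deletion tests were also adjusted after a first result.

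GET had 6 events in the 450 nt segment of the 2R region. The wt ratio and the GET events in the rest of the region predict 665, which argues against too few events in the GET libraries. The segment was chosen for its few GET events, so the low observed number (upper limit 13.1) adds nothing to this. A segment deleted from the RNA stays open: no GET gap spanned it (0 gaps), but from the 11 GET gaps of at least 200 nt in the region and the 133 GET events within 200 nt of the segment only 0.46 would be expected, so a count under 3 gaps, which was first to exclude a deletion, decides nothing. The opposite strand of the segment fell to 2.95% of wt (upper limit 17.2), which goes with an RNA that lacks the segment, but it held 8.44% to 17.3% as many events as the sense strand in the rest of the region and may follow it, so a loss of GET contacts stays open too. Whether the region is the mle gene, part of whose RNA an expressed construct could lack, is also open. Matching gaps to annotated intron lengths and spacings put mle first above the null matchings in 1 of 4 tolerance settings. In these 4 settings mle had 41, 31, 20 and 31 matches, and it had 0 in every null matching. Other genes led where mle had 41 and the last 31, with 101 and 552 matches. Where mle led with the first 31, of 42 in all, a null matching also gave another gene 31.

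XHet events differed 1.48-fold between the highest and lowest group, against 14.0-fold for all other events and 132-fold for the X region. The first ratio is 10.6% of the second, which argues against library depth alone. A background of near-constant yield that does not depend on the MLE variant stays open for XHet outside 2 windows. Windows XHet 192001 to 193000 and 193001 to 194000 (plus strand) differed in GET, which argues against such a background there. Their log2 fold changes were 2.50 and 3.59 against wt and 1.41 and 1.98 against the control. In raw events the window at 193001 was 28.9-fold of the control in GET, against 1.21-fold (KHR) to 3.07-fold (wt) in the other MLE groups. The position profile was compared with the control only in the XHet region, 190001 to 192000. It lay beyond 2 times the largest replicate distance (0.0526) in 1 of 5 MLE groups, wt, at 0.126. The next were HR at 0.0998, GET at 0.0936 and K at 0.0883, which all exceeded the largest replicate distance itself, while KHR at 0.0505 did not. No biological explanation was tested.

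The 3 windows higher in GET than in wt and K were over 2-fold above wt in 4 of 4 combinations of replicate and L or M files, which argues against a cause in 1 replicate or in only the L or only the M files. The windows were chosen as at least 4-fold higher in GET, so a gain over all files together was fixed by the choice. How that gain was spread over replicates, files and positions was not. In the 2R window 1 position held 53.6% of GET events, against 11.7% in the 3R window and 27.9% in the XHet window, so the bound set beforehand, under 50% in all 3, was not met. Without the fullest GET position, however, every GET library was at least 2.26-fold above every wt library in all 3 windows, and 817 of the 828 GET events at that position of the 2R window had distinct tags within their library. The folds without the fullest position argue against a single position as the whole cause. In the 2R window that position still holds most of the GET events. Only 1.21% of all event lines repeated a position and tag, so distinct tags were the rule at any position. The tag count therefore cannot tell whether amplified molecules played a part. The GET mutation itself was not tested apart from these explanations.

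A hypothesis is that the X region is roX2, the RNA in the series title. Its commonest gap, X 11473151 to 11473694, is 544 nt long, and roX2 has an annotated intron within 1 nt of that length, but 6 annotated genes of that chromosome and strand do, among them roX2, so this test leaves open whether the region is roX2.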
